A study of Mus musculus with 8 samples.

How the data were processed

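Per the labels, chromatin immunoprecipitation with an anti-V5 antibody was followed by sequencing for 5 ChIP libraries, each from the same number of cells, and 3 input libraries. PGCLCs were sorted for reporter fluorescence and mCherry, and ESCs for mCherry. Trim Galore 0.4.1, cutadapt 1.9.1, Bowtie 1.1.2, Picard 2.1.0, SAMtools 1.3, bedtools, MACS2 2.1.1.20160309 and HOMER 4.9.1 are named, without their settings, per the submitters' processing notes, as is the build mm10. The values the authors deposited are summit positions in bases, with no score, height, p-value or library. Which of the 5 ChIP libraries gave the peaks of the list, how they were joined, at which threshold, and how reads with several matches were treated is not given in the sources used here. Start and end are the same number for all 32927 summits, so whether positions count from 0 or 1 is open, which moves a distance by at most 1 base. Read depth is unknown, and a place without a summit may be unbound or below the authors' threshold.

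Summits were set against the 49980 genes of a RefSeq gene table for GRCm38, of which 21900 are protein-coding. The table used here holds the start and end of each gene but no strand, transcript or sequence. The plan had named transcription start sites, ungapped chromosome length and promoter GC content. They were replaced by either gene boundary, the span between the first and last annotated gene end, and matching on gene length and neighbour distance. Tests of GATA and other motifs and of repeats need sequence, tests of peak strength need a score, and comparisons of conditions need a library per peak, so these planned tests were not run.

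Boundary shares were compared with 1000 sets of random positions, the same number per chromosome within the annotated span, with two-sided permutation p-values. Assembly gaps within the span were not left out of the random positions. A gene was linked when a summit lay within 10 kb of a boundary. Each of 16 lists, written before the data were examined, was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment and a threshold of 0.05. The lists were also compared with 10000 random lists drawn from the same classes. These were 5 classes of gene length by 5 of distance to the nearer neighbouring gene. Draws came only from protein-coding genes outside the list, and the resampling p-values they gave are called permutation p below. The lists held meiotic prophase, oocyte, late germ cell, primordial germ cell, pluripotency, BMP, retinoic acid, male germ cell, erythroid, gonadal somatic, GATA, Polycomb, signalling (TGF-beta, WNT and Notch), housekeeping, olfactory receptor and Zfp genes. Names not matched in the table were Gcna and Mili in the late germ cell list, Dnmt3c in the male list and Ahsp in the erythroid list. Summits per chromosome were tested with a chi-square statistic and 100000 resamples. Shares carry exact 95% binomial intervals, which cover counting error only.

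Genes were named by a rule fixed before the data were examined: the 4 members of each list with the closest summit, 18 genes chosen in advance, and the 10 genes with most summits within 10 kb, ties taken alphabetically. Any other gene is said to be chosen after its values were seen. Alternatives covered other distances, all annotated genes, merged summits, single boundaries, matched lists and summits away from boundaries.

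The statistics were tested on simulated data over the same genes. Random summit sets gave a mean boundary share of 3.25%. Distances and counts matched a direct calculation for 300 of 300 summits and 300 of 300 genes. Of 100 unchanged lists of 24 genes, Fisher's test called 3 and the matched lists called 3, and of 100 lists raised by 30 percentage points Fisher's test called 100. The chromosome test called 5 of 100 uniform sets and 20 of 20 sets with 1 chromosome at a reduced share. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.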

Results

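The series asked where ZGLP1, a protein with GATA-like zinc fingers that the study's title ties to the oogenic fate, sits on the mouse genome. Cells carried a V5-tagged Zglp1 that was switched on with doxycycline (Dox), and chromatin was collected with an antibody against the V5 tag. The cells were primordial germ cell-like cells (PGCLCs), which are made in culture from embryonic stem cells (ESCs), and ESCs themselves. The 8 libraries comprised 5 ChIP libraries, 4 from PGCLCs and 1 from ESCs, and 3 input libraries. PGCLCs were taken on culture day 7 or 8 (c7 and c8), after Dox alone or Dox with retinoic acid (RA) from day 3, and ESCs after 24 h of both. Each group had 1 library, so there were no replicates.

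The values analysed here were the positions of 32927 peak summits, 1 base each, in a single list of all peaks. The list names no library and holds no height, so the comparisons of Dox with Dox and RA, of c7 with c8 and of PGCLCs with ESCs were not made, and the depth behind a summit is unknown. Every statement below is about where the summits of this list lie. Positions are on mm10 (GRCm38), and gene ends are those of the gene annotation of that build. Since the direction of genes was not used here, a boundary means either end of a gene, and a summit at a boundary can lie at its start or at its end.

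Summits gathered at the ends of protein-coding genes. Of 32912 summits on the autosomes and X, 13911 (42.3%, exact 95% binomial interval 41.7 to 42.8) lay within 1 kb of a boundary, against 3.24% ± 0.0984 (SD over 1000 random sets) of random positions, a ratio of 13.0. Within 500 bases the share was 31.6%, 18.6 times the random share. Summits inside protein-coding genes made up 64.9%, against 40.9% of random positions. Those inside a gene but over 10 kb from every protein-coding boundary made up 15.2%, against 28.8%. Summits over 50 kb from every boundary made up 10.3%, against 48.5%. For each of these classes the two-sided permutation p was 0.002, the smallest that 1000 sets can give. Summits also lay close to each other, with 15.5% of neighbouring pairs under 1 kb apart against 1.42% of random pairs, so the intervals, which treat summits as independent, are too narrow.

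**Figure D1:**
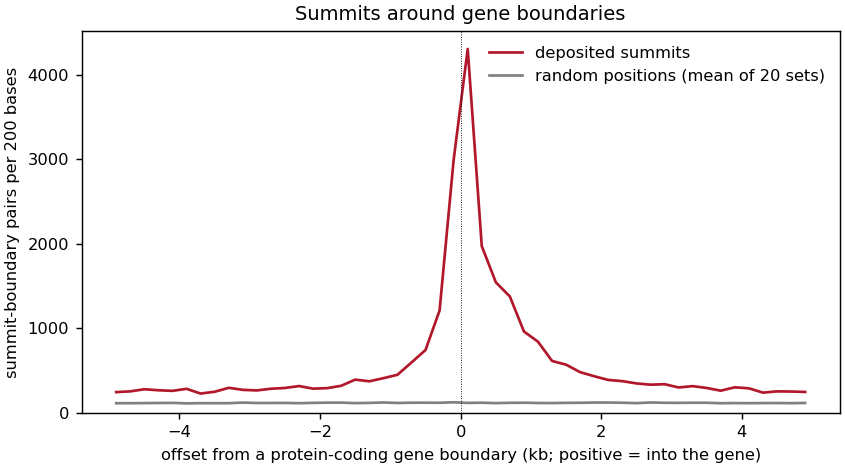
Number of summit-boundary pairs (y axis, per 200 bases) by offset from a protein-coding gene boundary (x axis, kb, positive into the gene), for the deposited summits (red) and the mean of 20 sets of random positions (grey). The highest bin, just inside the gene, holds 4308 pairs against 116.4 in random sets.

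Most genes with a summit at a boundary had it at a single end. Among 19190 protein-coding genes longer than 2 kb, 10453 (54.5%) had a summit within 1 kb of 1 boundary and 775 (4.04%) at both, where independent ends would give 9.78%. Pairs within 1 kb lay on the gene side in 62.8% of cases, with a median offset of 82 bases into the gene. Over all 21900 protein-coding genes, 11596 (52.9%) had a summit within 1 kb of a boundary and 14580 (66.6%) within 10 kb. The genes with most summits within 10 kb were Sfi1 with 18, Setd1b, a histone methyltransferase gene, with 15, and Midn with 14. Fbxl19, Hoxa3, Rhof and Septin1 followed with 13 each, Mllt6 with 12, and Bahcc1 and Ddx39b with 11. Setd1b and Rhof are neighbours and share summits, and the annotated span of Hoxa3 contains Hoxa5, with which it shares summits. Those of Sfi1 are part of a dense run of summits, taken up below, whose cause was not settled.

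Zglp1 itself (chromosome 9, 21062393 to 21067093) had 4 summits within 10 kb of its boundaries. They lay at 21062653, 21066202 and 21067005 inside the gene and at 21073450 outside it. The introduced V5-Zglp1 sequence can share reads with this gene, which was not examined. Among genes of meiotic entry, Stra8, a retinoic acid-responsive gene needed for meiotic initiation, had 3 summits, the closest 1773 bases inside its lower boundary (chromosome 6, 34920163 to 34939344). Rec8, the meiotic cohesin gene (chromosome 14, 55618002 to 55625395), had 3, the closest 178 bases inside. Sycp3, of the synaptonemal complex, had none within 10 kb, and its closest summit lay 30411 bases away.

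Of the oocyte transcription factors, Figla had 2 summits within 10 kb (closest 835 bases), Sohlh2 had 1 (156 bases) and Nobox had 1 (6718 bases), while Sohlh1 and Lhx8 had none (16744 and 51273 bases). The germ cell RNA-binding genes Ddx4 and Dazl had 2 each, at 175 and 160 bases. Gata2, which encodes a GATA factor, had 7, the BMP-responsive genes Id1 and Msx1 had 3 and 4, and Cyp26a1, which encodes a retinoic acid-degrading enzyme, had 6. Pou5f1 and Nanog, pluripotency factors, had 5 each. Actb, a widely used gene, had 8.

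**Figure D2:**
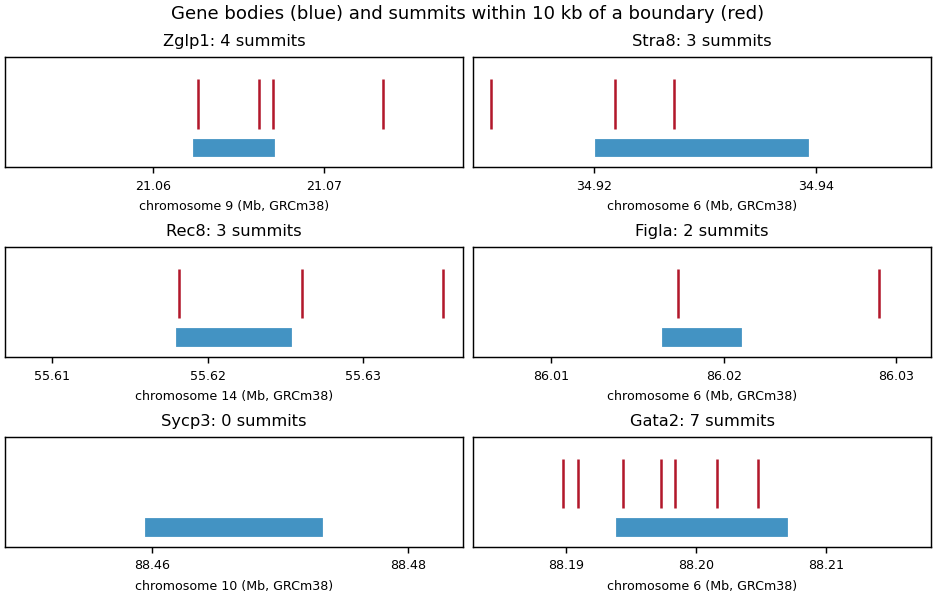
Maps of 6 loci, with the gene body in blue and each summit within 10 kb of a boundary as a red line, along the chromosome (x axis, Mb, GRCm38). Gata2 has 7 summits, Zglp1 has 4, Stra8 and Rec8 have 3 each, Figla has 2 and Sycp3 has 0.

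The title's question about germ cell fate was addressed with 16 gene lists, tested for a summit within 10 kb of a boundary against all other protein-coding genes (two-sided Fisher's exact test, Benjamini-Hochberg over the 16 lists). In 9 lists members had a summit more often and in 1 less often. Of the meiotic prophase list, 38 of 46 genes (82.6%) had a summit, against 66.5% of other genes (adjusted exact p = 0.034). Its members with the closest summits were Top6bl (Gm960 in the annotation), Mlh3, Iho1 and Prdm9, genes of meiotic recombination, at 5, 31, 34 and 36 bases. Random lists matched on gene length and on the distance to the neighbouring gene reached 81.3%, and the difference did not pass the test (permutation p = 1), and with summits over 1 kb from every boundary the list stood at 34.8% and other genes at 35.6%.

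The oocyte list, with 26 of 36 genes (72.2%, adjusted exact p = 0.636), did not pass the test, nor did the late germ cell list, with 24 of 29 (82.8%, adjusted exact p = 0.105), or the male germ cell list, with 20 of 25 (80.0%, adjusted exact p = 0.25). In the oocyte list the closest summits were those of Taf4b (11 bases), Pou6f1 (24 bases), Uchl1 (27 bases) and Stk31 (59 bases). In the late germ cell list they were those of Rpl10l, Mov10l1, Tdrkh and Tdrd1, at 14, 16, 17 and 19 bases. Mov10l1, Tdrkh and Tdrd1 act in the piRNA pathway.

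Genes of primordial germ cell specification had a summit in 21 of 24 cases (87.5%, adjusted exact p = 0.048), among them Ifitm3 (12 bases), Elf3 (17 bases), Prdm1 (32 bases) and Sox2 (42 bases). The call was lost at 1 kb, at 50 kb (13.7 percentage points over other genes, adjusted exact p = 0.19) and by nearest gene (19.8 points, adjusted exact p = 0.0793). Naive pluripotency genes had one in 23 of 24 cases (95.8%, adjusted exact p = 0.00522), with Klf5 (0 bases), Gbx2 (12 bases) and Fgf4 (17 bases) closest, a call lost at 50 kb (17.9 points, adjusted exact p = 0.0783). With only summits over 1 kb from every boundary, the shares were 83.3% and 95.8%, while that of other genes was 35.5%. The 2 lists, of 24 genes each, held 40 genes together. They share members such as Sox2 and are not separate results. With all summits within 10 kb, where the 2 lists stood at 87.5% and 95.8%, matched random lists reached 55.3% and 55.8%. Matched lists could include olfactory receptor genes, which rarely had a summit, and their effect on these shares was not examined. The permutation p was 0.0004 and 0.0002, the second the smallest that 10000 lists can give.

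Signalling lists also had summits more often than other genes. The BMP response list had 23 of 25 (92.0%, adjusted exact p = 0.0102), with Grem1 (21 bases) and Id3 (22 bases) closest. The retinoic acid response list had 25 of 27 (92.6%, adjusted exact p = 0.00834), among them Hoxa5 (98 bases) and Rdh10 (154 bases). The TGF-beta, WNT and Notch list had 38 of 41 (92.7%, adjusted exact p = 0.000679), among them Dkk1 (37 bases) and Hes1 (43 bases). Developmental regulators marked by Polycomb had 54 of 65 (83.1%, adjusted exact p = 0.00834), with Lhx3 (7 bases) and Neurog1 (76 bases) among the closest. The Zfp zinc finger genes had 332 of 397 (83.6%, adjusted exact p = 1.41e-13), 17.4 points above other genes, a call lost with summits over 1 kb from every boundary (39.3% against 35.5%, adjusted exact p = 0.182). On those summits the shares of the BMP, retinoic acid, Polycomb and TGF-beta, WNT and Notch lists were 76.0%, 74.1%, 64.6% and 58.5%.

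The housekeeping list had the highest share, with 32 of 32 genes (adjusted exact p = 2.12e-05), including Gapdh at 26 bases and Rps6 at 10 bases. At 1 kb it had 93.8%, above the meiotic (60.9%, adjusted exact p = 0.00282), oocyte (50.0%, adjusted exact p = 0.000477) and late germ cell (48.3%, adjusted exact p = 0.000477) lists by Fisher's exact test over 30 comparisons with it. The differences of the pluripotency list, at 87.5%, and of the primordial germ cell list, at 75.0%, did not pass the test (adjusted exact p = 0.642 and 0.0855). Olfactory receptor genes had a summit in 35 of 1110 cases (3.15%, against 70.0% of other genes), below every one of 10000 matched lists (permutation p = 0.0002). Gonadal somatic genes had 20 of 30 (66.7%, adjusted exact p = 1), GATA genes and partners 15 of 20 (75.0%, adjusted exact p = 0.557) and erythroid GATA targets 15 of 30 (50.0%, adjusted exact p = 0.105). At 1 kb the erythroid share was 13.3% against 53.0% of other genes (adjusted exact p = 3.75e-05).

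Genes are not replicates, neighbouring genes share summits, and 54 genes stand in more than 1 list, so these p-values say only that a list departs from other genes in this set of summits. At 1 kb the meiotic and retinoic acid lists lost their calls with smaller differences from other genes (7.94 and 2.61 percentage points), the primordial germ cell and BMP lists missed the threshold at about the same difference (22.1 and 23.1 points, adjusted exact p = 0.0783 and 0.0594), and the Polycomb list turned sign (-2.19 points).

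**Figure D3:**
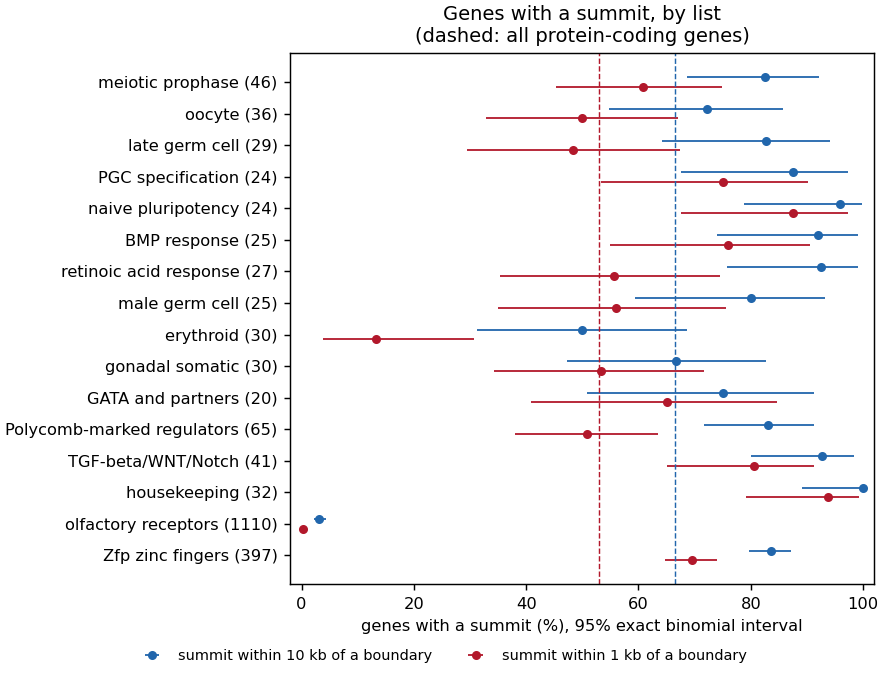
Percentage of genes with a summit (x axis) in each list (y axis, number of genes in brackets), within 10 kb (blue) and within 1 kb (red) of a boundary, with exact 95% binomial intervals and dashed lines for all protein-coding genes. The housekeeping list is highest at both distances, at 100% and 93.8%, and olfactory receptors are lowest.

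Chromosomes differed in how many summits they held. Chromosome 11 had the most per Mb of annotated span, 23.8, followed by chromosome 19 with 20.0 and chromosome 17 with 17.6, and chromosome 14 had the fewest among autosomes, 8.45. The X chromosome had 336 summits, 1.97 per Mb against 13.3 on autosomes, a ratio of 0.148. Per protein-coding gene the ratio was 0.221, with 0.348 summits on X and 1.58 on autosomes. Over the autosomes and X together, counts departed from annotated span (chi-square permutation p = 1e-05, the smallest that 100000 resamples can give). That test covers any difference between chromosomes, not X alone, and treats summits as independent. A summit within 1 kb of a boundary was found for 219 of 966 X-linked genes (22.7%) and 11370 of 20665 autosomal genes (55.0%, two-sided Fisher's exact p = 2.34e-89). The X-linked housekeeping genes Hprt and Pgk1, chosen after their values were seen, had a summit at 181 and 195 bases. Autosomes also differed among themselves, by up to 2.82-fold per Mb and 1.62-fold per gene (permutation p = 1e-05 for each).

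**Figure D4:**
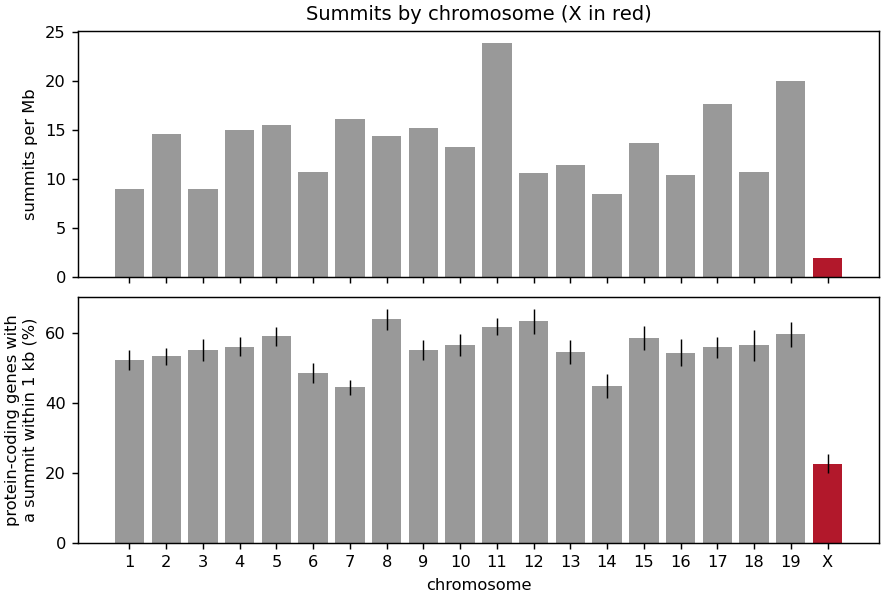
Summits per Mb of annotated span (top) and percentage of protein-coding genes with a summit within 1 kb of a boundary (bottom, exact 95% binomial intervals) for each autosome (grey) and X (red). X lies lowest in both, at 1.97 per Mb and 22.7%.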

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

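The test of X-linked partners of Y genes was chosen after the chromosome counts were seen, and that of widely used gene families before its own result. Summits on chromosomes outside the comparisons stood out because any were listed there. The mitochondrial genome had 5 summits, in ND1, ND2, ND4, ND5 and outside any gene. The Y chromosome had 10, of which 8 lay between 90739358 and 90805157 at its end, beside Mid1-ps1 and Gm52481, and 2 elsewhere.

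The low number of summits on X was weighed against the genes it carries. If gene content were the whole cause, families used in most cells would have summits as often on X as elsewhere. Their members had a summit within 1 kb in 25 of 39 cases on X (64.1%) and 619 of 698 on autosomes (88.7%), a difference of -24.6 percentage points (two-sided Fisher's exact p = 0.000105). This argues against gene content as the whole cause, although the gap is smaller than that over all genes. It assumes that the members on X are used as widely as those on autosomes, which was not examined. Fewer copies of X than of each autosome may contribute and cannot be told apart, because the list has no heights: of 4 widely used X genes with Y partners, Ddx3x, Eif2s3x and Kdm5c had a summit within 1 kb (3 of 4), Kdm6a had one at 2708 bases, and the Y partners had 0 of 4. The sex of the cells was not used here, so these counts do not decide how many X copies the cells held. No biological explanation was tested, since the list names no library and so no group.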

How the results depend on the processing

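Merging within 1 kb, single boundaries, leaving out the 2 densest windows, autosomal genes alone, summits away from boundaries, lists matched on gene length and neighbour distance, X by percent of genes and all settings for distal summits were alternatives chosen after seeing the data. Of 179 alternative values, 158 kept direction and side of the threshold or, for counts, stayed within 1.5 times. Another 9 kept direction but were no longer past the threshold, 2 came past it, 7 reversed and 3 counts moved. The cause was not tested. The boundary ratio stayed above random, from 4.65 within 5 kb to 18.6 within 500 bases, and the X ratio stayed under 1, at most 0.412. The number of lists linked more often, 9, became 7 at 50 kb and with summits away from boundaries, and 8 by nearest gene and against matched lists. At 1 kb it was 4, and 2 lists were linked less often in place of 1. In percentage points over other genes, the 1 kb values were 7.94 (meiotic), 22.1 (primordial germ cell), 23.1 (BMP) and 2.61 (retinoic acid), no longer past the threshold, -39.7 (erythroid), now past it, and -2.19 (Polycomb), -2.96 (oocyte) and -4.68 (late germ cell), reversed, the last pair past the threshold in neither setting. At 50 kb, primordial germ cell (13.7) and pluripotency (17.9) lists lost their calls. By nearest gene, 2 lists were linked less often, the primordial germ cell list (19.8) lost its call, the erythroid list (-26.9) gained one and the gonadal somatic list (-0.188) reversed, far from the threshold. With summits over 1 kb from every boundary, the meiotic (-0.79), late germ cell (-8.0) and erythroid (1.1) lists reversed and the Zfp list (3.79) lost its call. The primordial germ cell (47.8), pluripotency (60.3), BMP (40.5), retinoic acid (38.5), Polycomb (29.1), signalling (23.0) and housekeeping (23.8) lists stayed past the threshold. These differences are not comparable in size with those at 10 kb, since most other genes had a summit there (66.5%) and fewer in this setting (35.5%). Against matched lists the meiotic difference was 1.28. Merging within 1 kb left 27811 summits. Merging within 100 bases joined none, so the 20 values under it, counted among the 158, test nothing. Leaving out the 2 densest windows removed 0.249% of summits, so the values under it could hardly move and are weak tests. Merging within 1 kb keeps a summit of every run, so links within 10 kb could change little. The retinoic acid difference went from 26.05 to 22.37 points under it. Not run were all alternatives that need a score, strand, sequence or libraries per peak: stricter thresholds, 1 start site per gene, every motif and repeat setting, GC strata, CpG-rich promoters and condition overlaps. No paired analysis was possible because each group had 1 library and the list names none. Unknown depth limits every absence of a summit.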

Other observations

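Gene families by symbol, the dense runs of summits, the comparisons with housekeeping genes and the tests of the oocyte list, of reporter loci, of distal summits at other lists and of distal summits against housekeeping genes were chosen after results were seen, and the matched tests of distal summits at pluripotency and late germ cell genes before theirs. Among 109 families of at least 20 genes sharing the start of a symbol, 40 had a summit within 1 kb of a boundary more often than other genes and 33 less often (Fisher's exact test, Benjamini-Hochberg). Mitochondrial ribosome genes (Mrps) had 29 of 29, RNA polymerase genes (Polr) 28 of 28, Mediator genes (Med) 29 of 30 and ribosomal genes (Rpl) 48 of 53. Vomeronasal receptors (Vmn) had 4 of 355, keratin-associated genes (Krtap) 0 of 56, the X-linked homeobox family Rhox 0 of 33 and Pramel genes 3 of 46. Members of such clustered families can be near-identical, and how reads with several matches were treated is not given.

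Some loci, chosen after their values were seen, had many summits away from boundaries. Esrrb had 17 summits inside the gene and Slc2a3 15. Within 50 kb, counting summits over 1 kb from every boundary, Sfi1 had 48, Bahcc1 22, Slc2a3 20, Prdm1 19, Mllt6 and Smad7 17 each, Midn 16, and Nanog and Dppa3, which lie on the same stretch of chromosome 6 as Slc2a3, 15 each.

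Runs of closely spaced summits lay at Sfi1 (chromosome 11, 3123805 to 3203120, 51 summits) and on chromosome 9 (3000461 to 3038082, 31 summits, no protein-coding gene). Together they held 82 summits, 0.249% of the list, of which 12.2% lay within 1 kb of a gene boundary, against 47.6% of 429 in the 18 next densest windows (two-sided Fisher's exact p = 3.7e-10). That test treats summits as independent, although those within a window are neighbours, so its p-value is too small. By window the share was 17.65% at Sfi1 and 3.23% on chromosome 9, while the 18 others ranged from 18.18% to 92%. Sfi1 thus lay only just below the lowest of them. The coefficient of variation of summit spacing was 0.887 at Sfi1 and 0.7 on chromosome 9, where the other windows ranged from 0.708 upwards with a median of 1.09. Sequence present in more copies than the assembly holds may contribute and cannot be told apart. Even tiling would put both values below every other window, which held on chromosome 9 but not at Sfi1. The 18 summits within 10 kb of the boundaries of Sfi1 are all part of the run there.

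Distal summits, those over 1 kb from every protein-coding boundary, were counted within 50 kb of each gene. In 8 of 16 lists they were more numerous than in matched lists and in 1, the olfactory receptors, fewer (permutation test, Benjamini-Hochberg). Means were 6.42 per gene against 1.75 for primordial germ cell genes, 5.25 against 1.68 for pluripotency, 4.67 against 2.08 for retinoic acid and 4.08 against 1.38 for BMP response. They were 3.65 against 1.88 for GATA genes and partners, 3.22 against 1.4 for Polycomb-marked genes, 3.15 against 1.99 for signalling and 4.25 against 2.41 for housekeeping genes. A gathering at late germ cell genes was not found, their mean being 1.31 ± 1.39 (SD over 29 genes) against 2.11 (permutation p = 0.0752).

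Germ cell lists near summits were weighed against a general preference for widely used genes and a selection for the oocyte programme. The first may contribute and cannot be told apart: 93.8% of the housekeeping list had a summit within 1 kb, but that share does not say why genes that are not widely used have one. With summits over 1 kb from every boundary, 83.3% of the primordial germ cell list, 95.8% of the pluripotency list and 59.4% of the housekeeping list had a summit within 10 kb, shares that were not tested against each other. Selection for the oocyte programme stays open too, the list exceeding other genes by 5.66 percentage points and matched lists by 7.54 (permutation p = 0.409), with 2.75 distal summits per gene against 1.97 (permutation p = 0.0766). Binding in a single condition was not tested, because the list names no library.

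The distal summits at pluripotency and primordial germ cell genes, an excess these lists shared with others, were weighed in the same way. Neighbourhood size was measured by gene length and the gap to the nearer neighbouring gene. The mean was 5.25 ± 3.53 (SD over 24 genes) at pluripotency genes, against 1.68 in matched lists (permutation p = 0.0002). This argues against neighbourhood size, so measured, as the whole cause. The gap on the other side, which the count within 50 kb also reaches, was not matched. Extra copies of sequence around the reporter genes Prdm1 and Dppa3 were a candidate explanation. Without these genes and Nanog the mean of both lists was 4.95, against 1.75 in matched lists (permutation p = 0.0002), where all 40 genes gave 5.8. This argues against such copies as the cause of the excess at the other genes, and does not bear on those loci themselves. Active gene neighbourhoods in general stay open and cannot be told apart: the lists exceeded the housekeeping list by 1.55 summits per gene (permutation p = 0.107). No biological explanation was tested, since no group can be separated in the list.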
